A study of Mus musculus with 96 samples.

How the data were processed

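Gene expression was measured on 2-colour arrays of 16281 probes in RAW 264.7 cells, with treated RNA in 1 dye and untreated RNA of the same set and time in the other. The 96 samples fall into 16 groups of treatment and time, each of 3 sets in 2 dye orientations, which gives 48 set values. Groups, dye orientation, doses and times were taken from the labels. What was done to the arrays before the values were made, such as image analysis, background correction and normalisation, is not given in the sources used here. The deposited log2 values are read as the ratio of Cy5 to Cy3 of each array, with the channel roles per the labels. The scale was read from the values: the largest, 6.643856, is log2 of 100, and 14 values sit on it. Direction rests on the channel labels and on the checks below. How the values were centred stays unknown: the median of every array was exactly 0 with zeros included, and the median of nonzero values lay between -0.0442 and 0.0241. Per-sample columns not used here number 0.

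Values of exactly 0, between 1277 and 2773 per array, were read as no measurement, a choice made after the values were seen, with zeros kept as 0 as an added alternative. On every array, 753 probes were at 0. Arrays with treated RNA in Cy3 had their sign turned, and a set value was the mean of both orientations where both had a value. A probe was tested if every group had a value in at least 2 of its 3 sets. This kept 13698 probes and left out 2583. Gene names came from the platform annotation of 2016, brought to current symbols with the mouse RefSeq gene table, and no genome coordinates were used. Of all probes, 13738 had 1 gene, 52 several and 2491 none here. Probes of 1 gene were averaged, which affected 1914 genes and gave 9755 named genes and 1838 unnamed probes, 11593 in all. Of their set values 5704 (1.03%) were missing.

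The tests used limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8), and plots used matplotlib 3.10.9 in Python 3.11.15. A linear model with 1 mean per group was fitted to all 48 set values with empirical Bayes moderation (32 residual degrees of freedom, prior degrees of freedom 5.887). Each response was tested against 0, LPS with a second ligand against LPS, the joint response against the sum of the single responses, and the LPS times against each other by an F test. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The median residual SD was 0.196. For the responses of 2 ligands, correlations and covariances across genes were set against simulations with no effect.

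The groups, tests, alternatives, the 17 gene lists and the cell type markers were fixed before the data were examined. The named genes follow a rule fixed then: per comparison, among genes with an adjusted p under 0.05 and the same sign on all 6 arrays (for differences, in all 3 sets), the 10 largest rises and 5 largest falls, plus list members and the genes of the direction check. The lists reported cover early response transcription factors, NF-kB family and feedback, cytokines and chemokines, type I interferon targets, MHC and antigen processing, MAPK and G protein feedback, calcium and cAMP responsive genes, purinergic receptors and ectoenzymes, Nrf2 and oxidative stress, unfolded protein and amino acid stress, heat shock, cholesterol biosynthesis, glycolysis and hypoxia, cell cycle, macrophage surface and lysosome, and housekeeping. Another list is not reported here. Lists were tested with camera (preset correlation 0.01), adjusted over all 17 lists of each comparison. Of 208 calls over the 17 lists, 120 held with an estimated correlation, and 161 were also called by fry, which asks whether the genes of a list move 1 way on balance.

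Dye-swapped arrays of 1 set should correlate below 0 before turning. The correlations ran from -0.784 to 0.396, and 10 of 48 pairs lay above 0, all in 2MA groups or in LPS and IFNG groups at 30 min or 1 h. The pairs of the 4 h groups with LPS ran from -0.784 to -0.424. After turning, known LPS and IFNG genes were read as given in the report. A dye effect was found in 9465 of 11593 genes in a model of all arrays, where the arrays of 1 set correlated at 0.247, and the mean of both orientations removes it. Pairing of sets was checked by whether deviations from the group means, matched by set number, correlated above 0.1 across genes in every pair of the compared groups. This held for LPS with a second ligand against LPS, for the sum of LPS and IFNG at 1 h (from 0.109) and 4 h (from 0.258) and of LPS and 2MA at 2 h (from 0.15) and 4 h (from 0.238). It did not hold for the sum of LPS and IFNG at 2 h (lowest -0.0316), of LPS and 2MA at 1 h (lowest -0.0312) or the LPS times (from -0.301 to 0.42). Residuals of the same set and time correlated at 0.414 on average, those of the same set at other times at 0.152.

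The calls were tested on simulated data with the real groups and sets, with errors drawn independently for each set value. The correlation of residuals within a set and time (0.414 on average) was not simulated. The shares that follow may therefore differ in the real data, above all for differences from LPS and deviations from the sum. At a 2-fold change, 98.5% of changed genes were found for LPS at 1 h, 95.5% for the difference from LPS, 82.1% for the deviation from the sum and 92.5% for the LPS times. At 1.5-fold these shares were 74.6%, 50.7%, 28.4% and 59.7%. Wrong calls made up 4.71% to 7.95% of the calls. Alternatives tried were scaling arrays to equal spread, centring each on its median, all 96 arrays with a dye term, each probe alone, probes with a value on all arrays, a robust prior, blocks of set number or of set within time, the groups of a comparison alone, each set left out in turn and, added after seeing the data, zeros kept as 0. The other log base was not used, since the values settle it.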

Results

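RAW 264.7 cells, a mouse macrophage-like line, were exposed to 1 of 3 ligands, or to LPS with either of the others, and their RNA was compared with RNA of untreated cells on 2-colour arrays. LPS, the lipopolysaccharide of Gram-negative bacteria that signals through Toll-like receptor 4, was given at 100 ng (the labels state no volume) with 100 pM LPS-binding protein. Interferon gamma (IFNG) was given at 5 nM. 2-methyl-thio-ATP (2MA), an ATP analogue that acts on P2 purinergic receptors, was given at 500 uM by the channel labels, although 1 sample has 500 nM in its description. Cells were collected after 1, 2 and 4 h, and after 30 min with LPS alone. Each of the 16 combinations of treatment and time comprised 3 sets, and each set was hybridised in both dye orientations, which gave 96 arrays. Between 13508 and 15004 of 16281 probes had a value on an array (median 14750). The number of arrays limits the precision. The median standard error was 0.112 for a mean response, 0.16 for a difference from LPS and 0.197 for a deviation from the sum of 2 responses, all in log2 units.

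Responses are log2 ratios of treated to untreated cells, given as mean ± SD over 3 sets. Differences between treatments and deviations from a sum are given ± SE. Tests ran on 9755 named genes and 1838 probes without a name here, and both are counted as genes. The labels do not say that the sets were separate cultures, so the p-values measure the spread between sets, which may be technical. That spread is pooled over all 16 groups, while the SD beside a response is that of its own group. A group whose sets differ more than that is tested too leniently. Egr2 with 2MA at 2 h had an SD of 1.60 over 3 sets but was tested with an SE of 0.45. They also do not say whether treatments share the untreated RNA of a set and time. Shared RNA would enter the differences from LPS and the deviations from a sum, and residuals of the same set and time correlated at 0.414 on average. Known LPS genes (Tnf, Il1b, Ccl4 and Ptgs2) were above 0 on 6 of 6 arrays at each LPS time, and Irf1 and Socs1 were above 0 on 6 of 6 arrays at each IFNG time. Nfkbia, which encodes the NF-kB inhibitor IkB alpha, had a value on only 4 LPS arrays at 1 h, all above 0. Cxcl2 was above 0 on 4 of 4 LPS arrays with a value at 1 h but had a mean of -1.27 over the 2 arrays with a value at 4 h. Neither entered the tests.

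Within 30 min, LPS raised immediate-early transcription factors and the first inflammatory transcripts. Egr1, an early growth response transcription factor, rose by 4.94 ± 0.47 and Egr2 by 3.99 ± 0.57. Tnf rose by 3.97 ± 0.37, and Zfp36, which promotes decay of Tnf mRNA, by 3.87 ± 0.35. The atypical IkB protein Nfkbiz rose by 4.35 ± 0.59 (adjusted p = 3.88e-15), and Dusp1, a phosphatase that inactivates MAP kinases, by 3.73 ± 0.66. Of the early response transcription factors, 14 of 20 rose (16 adjusted over the list alone, camera adjusted p = 3.91e-92). Of the NF-kB family and feedback genes, 5 of 18 rose (11 adjusted over the list alone, camera adjusted p = 9.95e-40). Of the calcium and cAMP responsive genes, 7 of 18 rose (9 adjusted over the list alone, camera adjusted p = 2.17e-33). Of the MAPK and G protein feedback genes, 3 of 13 rose (4 adjusted over the list alone, camera adjusted p = 1.11e-08). Of the cytokines and chemokines, 4 of 26 rose (4 adjusted over the list alone, camera adjusted p = 2.03e-10). Of the type I interferon targets only Ifit3 passed the test (3.03 ± 0.54), through a probe that differs in time course from the other Ifit3 probe, and the list gave camera adjusted p = 0.0684. Falls were fewer and smaller, led by Zfp398 (-1.53 ± 0.078), the small nucleolar RNA host gene Snhg5 (-1.31 ± 0.20) and Agfg2 (-1.18 ± 0.36). In all, 121 genes changed (84 up and 37 down), 52 of them by at least 2-fold, and 76 changed without set 3.

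At 1 h of LPS most early response factors were up, and more cytokine transcripts had risen than at 30 min. Fos, at 1.57 ± 0.22 at 30 min, did not pass the test at 1 h (0.06 ± 0.30). Nfkbiz rose by 5.04 ± 0.50, Il1b by 2.90 ± 0.40 and Cd83, a surface protein of activated antigen-presenting cells, by 3.41 ± 0.21. Tnfaip3, a feedback inhibitor of NF-kB, rose by 1.99 ± 0.44 and the NF-kB subunit Relb by 1.19 ± 0.47. Among NF-kB family and feedback genes, 16 of 18 rose (17 adjusted over the list alone, camera adjusted p = 1.48e-48). Among early response transcription factors, 15 of 20 rose (15 adjusted over the list alone, camera adjusted p = 4.01e-36). Among calcium and cAMP responsive genes, 11 of 18 rose (11 adjusted over the list alone, camera adjusted p = 1.66e-21). Among cytokines and chemokines, 12 of 26 rose (12 adjusted over the list alone, camera adjusted p = 5.12e-17). Of the cholesterol biosynthesis genes, 4 of 8 rose (4 adjusted over the list alone, camera adjusted p = 0.00056). Txnip, which binds thioredoxin and restrains glucose uptake, fell by 1.93 ± 0.32, and the cannabinoid receptor gene Cnr2 fell by 1.14 ± 0.085. Of the type I interferon targets, 4 of 22 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.00208, and adjusted p = 0.296 with an estimated correlation). Of the unfolded protein and amino acid stress genes, 2 of 15 rose (6 adjusted over the list alone, camera adjusted p = 0.00208, and adjusted p = 0.202 with an estimated correlation). In all, 650 genes changed (363 up and 287 down), 125 of them by at least 2-fold. Leaving out set 1 gave 273 genes and leaving out set 2 gave 410.

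By 2 h of LPS the response had broadened to interferon-induced antiviral genes. Ifit1, which binds viral RNA, rose by 3.63 ± 0.38 (adjusted p = 3.12e-19), Il1b by 4.58 ± 0.20, Il6 by 2.01 ± 0.42 and Ifnb1, which encodes interferon beta, by 3.42 ± 0.20. For the NF-kB family and feedback genes, 18 of 18 rose (18 adjusted over the list alone, camera adjusted p = 1.76e-42). Among type I interferon targets, 21 of 22 rose (21 adjusted over the list alone, camera adjusted p = 1.42e-33). Early response factors went both ways, with Atf3 at 1.59 ± 0.42 and Jun at -1.02 ± 0.21. For the early response transcription factors, 10 of 20 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 6.67e-06, and adjusted p = 0.0571 with an estimated correlation). Of the cell cycle genes, 7 of 24 fell (9 adjusted over the list alone, camera adjusted p = 0.000111). Slc40a1, the iron exporter ferroportin, fell by 2.07 ± 0.71, and Tsc22d3, a glucocorticoid-induced gene, fell by 1.57 ± 0.36. In all, 1857 genes changed (909 up and 948 down), 256 of them by at least 2-fold, and 999 changed without set 1.

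At 4 h of LPS, type I interferon targets and cytokines rose, and cell cycle genes fell. Cmpk2 rose by 5.47 ± 0.29, Ifit2 by 5.27 ± 0.33, Gbp3 by 4.99 ± 0.53 (adjusted p = 2.75e-22), the acute-phase gene Saa3 by 4.91 ± 0.13 and Il6 by 4.50 ± 0.10. For the type I interferon targets, 22 of 22 rose (22 adjusted over the list alone, camera adjusted p = 2.29e-39). Of the MHC and antigen processing genes, 12 of 15 rose (12 adjusted over the list alone, camera adjusted p = 3e-08). Of the NF-kB family and feedback genes, 17 of 18 rose (18 adjusted over the list alone, camera adjusted p = 3.07e-22). For the cytokines and chemokines, 19 of 26 rose (19 adjusted over the list alone, camera adjusted p = 7.39e-21). Among cell cycle genes, 20 of 24 fell (21 adjusted over the list alone, camera adjusted p = 2.96e-13). Falling members included Cdk1 (-0.46 ± 0.24), the replication licensing gene Mcm5 (-0.45 ± 0.14) and Ccne2 (-1.02 ± 0.12). Of the macrophage surface and lysosome genes, 8 of 25 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.0452, and adjusted p = 0.232 with an estimated correlation, and adjusted p = 0.0501 on centred arrays). The macrophage marker Adgre1 rose by 0.94 ± 0.25 while Csf1r, the receptor for colony-stimulating factor 1, fell by 0.94 ± 0.23. Of the early response transcription factors, 8 of 20 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.000628, and adjusted p = 0.16 with an estimated correlation). For the calcium and cAMP responsive genes, 6 of 18 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00556, and adjusted p = 0.146 with an estimated correlation). In all, 3315 genes changed (1474 up and 1841 down), 558 of them by at least 2-fold, and 2136 changed without set 1.

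**Figure D1:**
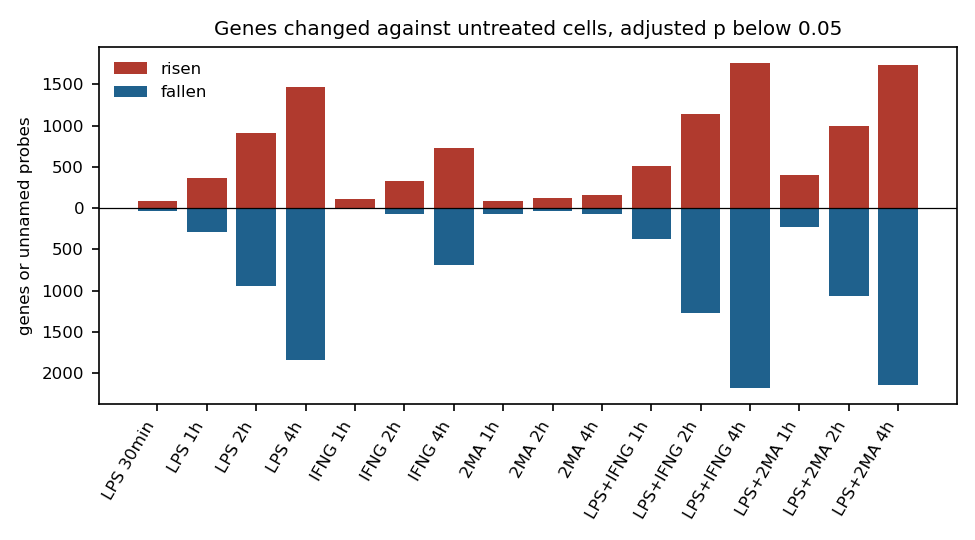
Number of genes or unnamed probes that passed the test against untreated cells (y), risen above and fallen below the axis, for the 16 treatment-time groups (x) of 3 sets each. Counts grew with time for LPS from 121 at 30 min to 3315 at 4 h, and stayed between 154 and 232 for 2MA alone.

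Most of the LPS response built up over the time course. A test over the 4 LPS times found 1941 genes whose response differed with time, and 789 without set 1. Among them, the largest rise came at 4 h for 758 genes, at 2 h for 155, at 1 h for 70 and at 30 min for 16. The largest fall came at 4 h for 761 genes, at 2 h for 120, at 1 h for 47 and at 30 min for 14. Of the 84 genes risen at 30 min, 70 were also up at 1 h, 66 at 2 h and 60 at 4 h. Egr1 stood at 4.94 ± 0.47 at 30 min, at 0.61 ± 1.69 at 2 h, where it did not pass the test, and at 2.64 ± 0.64 at 4 h. Ifit1 went from 0.84 ± 0.22 at 1 h to 4.44 ± 0.075 at 4 h.

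**Figure D2:**
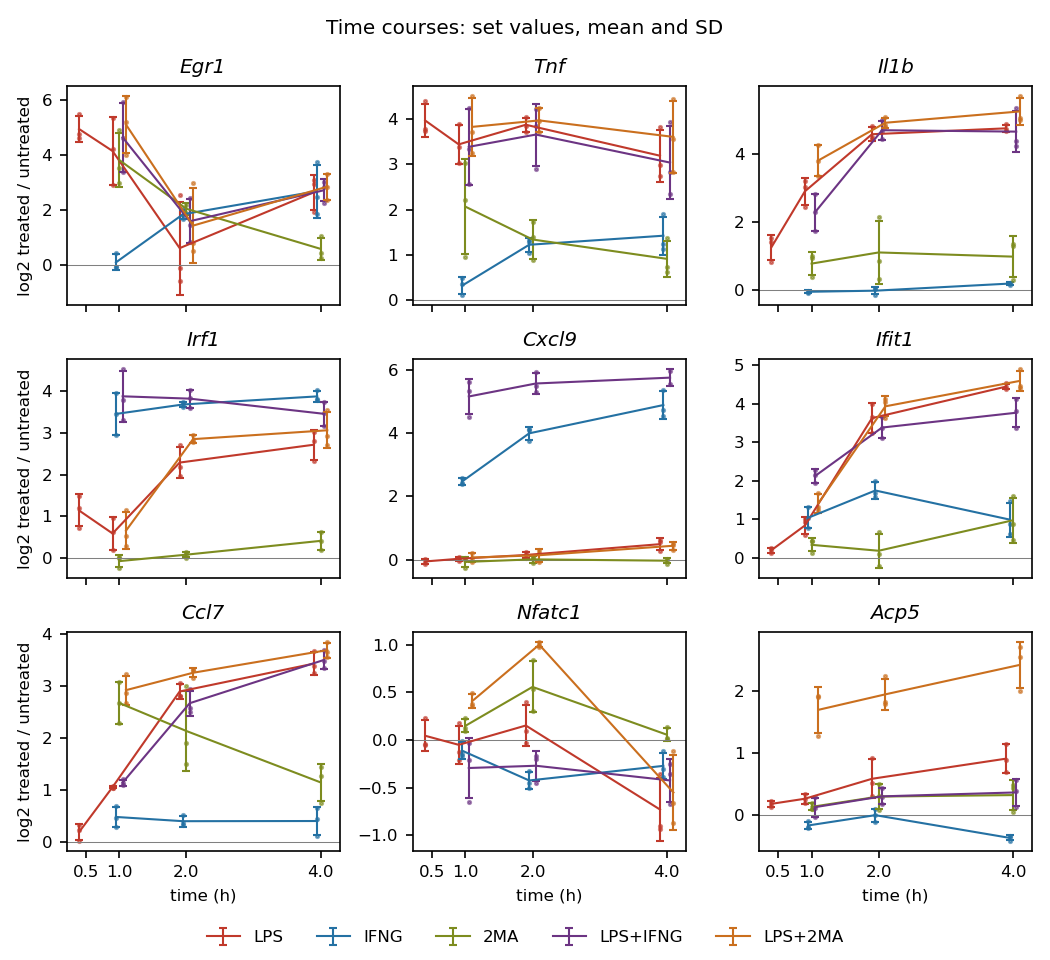
Time courses of 9 genes after each treatment, as log2 of treated over untreated cells (y) against time in h (x, treatments shifted slightly sideways), with points for single sets and lines joining means with SD bars. Among the times of LPS alone, Egr1 was highest at 30 min (4.94), Cxcl9 reached 4.90 with IFNG against 0.49 with LPS at 4 h, and Acp5 was highest with LPS and 2MA together.

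At 1 h of IFNG, more genes rose than fell. Irf1, an interferon-induced transcription factor, rose by 3.44 ± 0.50, and Socs1, a feedback inhibitor of cytokine signalling, by 2.96 ± 0.18 (adjusted p = 1.57e-18). The immunity-related GTPases Irgm2 and Iigp1 rose by 3.09 ± 0.15 and 2.96 ± 0.40, and the chemokine Cxcl9 by 2.48 ± 0.11. Of the type I interferon targets, 7 of 22 rose (16 adjusted over the list alone, camera adjusted p = 7.5e-36). Myc fell by 1.43 ± 0.34 and the G protein regulator Rgs2 fell by 1.00 ± 0.33. Among MAPK and G protein feedback genes, 3 of 13 fell (3 adjusted over the list alone, camera adjusted p = 0.00474, and adjusted p = 0.118 with an estimated correlation). Among NF-kB family and feedback genes, 1 of 18 rose (3 adjusted over the list alone, camera adjusted p = 0.0379, and adjusted p = 0.493 with an estimated correlation). In all, 131 genes changed (116 up and 15 down), 44 of them by at least 2-fold. The count was 80 without set 1 and 83 without set 2.

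At 2 h of IFNG more genes had risen than at 1 h. Iigp1 rose by 4.92 ± 0.33, Tgtp1 by 4.82 ± 0.47, Cxcl9 by 4.00 ± 0.20 and Cd274, which encodes the checkpoint ligand PD-L1, by 3.54 ± 0.23. Among type I interferon targets, 17 of 22 rose (20 adjusted over the list alone, camera adjusted p = 2.11e-55). Among MHC and antigen processing genes, 8 of 15 rose (8 adjusted over the list alone, camera adjusted p = 4.14e-09). For the NF-kB family and feedback genes, 6 of 18 rose (8 adjusted over the list alone, camera adjusted p = 8.05e-10). Cd40, a co-stimulatory receptor on that list, rose by 2.02 ± 0.47. Of the oxidative stress genes, 2 of 10 fell (2 adjusted over the list alone, camera adjusted p = 0.00333). They included Gclc, a glutathione synthesis gene, at -0.52 ± 0.14 and Osgin1 at -0.60 ± 0.39. In all, 398 genes changed (328 up and 70 down), 125 of them by at least 2-fold. The count was 220 without set 1 and 260 without set 2.

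At 4 h of IFNG, antigen processing genes had risen and cell cycle genes had fallen. Tgtp1 rose by 5.57 ± 0.27, Gbp8 by 5.01 ± 0.28 and Cxcl9 by 4.90 ± 0.43 (adjusted p = 1.38e-26). The peptide transporter Tap1 rose by 2.21 ± 0.13 and the class II chaperone Cd74 by 0.80 ± 0.23. For the MHC and antigen processing genes, 12 of 15 rose (13 adjusted over the list alone, camera adjusted p = 1.07e-18). For the type I interferon targets, 17 of 22 rose (17 adjusted over the list alone, camera adjusted p = 1.56e-25). Of the NF-kB family and feedback genes, 15 of 18 rose (15 adjusted over the list alone, camera adjusted p = 4.17e-21). For the cell cycle genes, 13 of 24 fell (19 adjusted over the list alone, camera adjusted p = 3.43e-12). The replication licensing gene Cdc6 fell by 0.90 ± 0.092 and the fractalkine receptor Cx3cr1 fell by 1.59 ± 0.19. Among early response transcription factors, 9 of 20 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 1.65e-05, and adjusted p = 0.0601 with an estimated correlation). In all, 1426 genes changed (731 up and 695 down), 216 of them by at least 2-fold, and 826 changed without set 1.

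The purinergic ligand 2MA alone raised early response and calcium-linked genes at 1 h. Egr2 rose by 4.40 ± 1.07, Egr1 by 3.81 ± 0.99, Myc by 2.54 ± 0.42 and Rcan1, an inhibitor of calcineurin, by 2.30 ± 0.46. Of the calcium and cAMP responsive genes, 10 of 18 rose (13 adjusted over the list alone, camera adjusted p = 1.09e-28). For the early response transcription factors, 11 of 20 rose (17 adjusted over the list alone, camera adjusted p = 3.47e-35). For the MAPK and G protein feedback genes, 4 of 13 rose (7 adjusted over the list alone, camera adjusted p = 4.01e-10). The chemokine gene Ccl7 rose by 2.67 ± 0.39 (adjusted p = 2.64e-15) as the mean of 3 probes, of which 1 stayed at -0.05. Tnf rose by 2.06 ± 1.06. Of the cytokines and chemokines, 3 of 26 rose (4 adjusted over the list alone, camera adjusted p = 0.000108, and adjusted p = 0.0509 with an estimated correlation). Among NF-kB family and feedback genes, 2 of 18 rose (4 adjusted over the list alone, camera adjusted p = 0.00268, and adjusted p = 0.379 with an estimated correlation). Among unfolded protein and amino acid stress genes, 1 of 15 rose (1 adjusted over the list alone, camera adjusted p = 0.0337, and adjusted p = 0.474 with an estimated correlation). Id2, an inhibitor of basic helix-loop-helix factors, fell by 1.19 ± 0.29. In all, 163 genes changed (92 up and 71 down), 39 of them by at least 2-fold. The count was 20 without set 1 and 351 without set 2, and responses of sets 2 and 3 correlated at 0.124 across genes, which are not independent replicates.

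At 2 h of 2MA fewer early response genes were up than at 1 h, and at 4 h type I interferon targets had risen. At 2 h Egr2 was at 2.55 ± 1.60, Egr3 at 1.73 ± 1.04, Rcan1 at 1.89 ± 0.93 and Ocstamp, which takes part in osteoclast fusion, at 1.67 ± 0.88, while Id3 fell by 0.78 ± 0.53. At 4 h the antiviral genes Ifit1 and Isg15 were at 0.98 ± 0.58 and 0.97 ± 0.62 and the polyamine synthesis gene Odc1 at 1.17 ± 0.54. Of the early response transcription factors at 2 h, 5 of 20 rose (11 adjusted over the list alone, camera adjusted p = 1.43e-19). For the NF-kB family and feedback genes at 2 h, 4 of 18 rose (9 adjusted over the list alone, camera adjusted p = 3.7e-13). Of the NF-kB family and feedback genes at 4 h, 6 of 18 rose (9 adjusted over the list alone, camera adjusted p = 8.84e-11). Of the type I interferon targets at 4 h, 10 of 22 rose (15 adjusted over the list alone, camera adjusted p = 3.22e-22). Among calcium and cAMP responsive genes at 2 h, 4 of 18 rose (10 adjusted over the list alone, camera adjusted p = 6.94e-18). For the calcium and cAMP responsive genes at 4 h, 1 of 18 rose (3 adjusted over the list alone, camera adjusted p = 0.000171). Of the cell cycle genes at 4 h, 2 of 24 fell (5 adjusted over the list alone, camera adjusted p = 2.05e-06). At 2 h 154 genes changed (119 up and 35 down), 38 of them by at least 2-fold, and at 4 h 232 genes changed (165 up and 67 down), 18 of them by at least 2-fold. Without set 1 the counts were 12 and 13. With only the groups of the comparison in the model they were 14 and 36. Across genes, responses of sets 2 and 3 correlated at -0.33 at 2 h and -0.03 at 4 h, and those of sets 1 and 2 at 0.0713 and 0.0942.

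Cells given LPS and IFNG together showed rises of NF-kB family genes, cytokines and type I interferon targets. At 1 h Cxcl9 rose by 5.17 ± 0.57 (adjusted p = 1.98e-27), Nfkbiz by 5.04 ± 0.60, the coagulation initiator F3 by 4.15 ± 0.38 and Irf1 by 3.87 ± 0.61. Among NF-kB family and feedback genes at 1 h, 16 of 18 rose (17 adjusted over the list alone, camera adjusted p = 3.55e-42). Among early response transcription factors at 1 h, 15 of 20 rose (16 adjusted over the list alone, camera adjusted p = 3.17e-30). Among type I interferon targets at 1 h, 16 of 22 rose (19 adjusted over the list alone, camera adjusted p = 3.17e-30). At 4 h Iigp1 rose by 5.68 ± 0.22, Gbp3 by 5.59 ± 0.24, Cd40 by 5.44 ± 0.38 and Il6 by 5.14 ± 0.59. Among cytokines and chemokines at 4 h, 18 of 26 rose (18 adjusted over the list alone, camera adjusted p = 4.37e-16). Among cell cycle genes at 2 h, 15 of 24 fell (16 adjusted over the list alone, camera adjusted p = 2.52e-09). For the cell cycle genes at 4 h, 21 of 24 fell (21 adjusted over the list alone, camera adjusted p = 3.05e-13). Esco2, a cohesin acetyltransferase, fell by 2.20 ± 0.45 at 4 h and Mcm5 fell by 0.55 ± 0.21. Among cholesterol biosynthesis genes at 4 h, 1 of 8 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.0272, and adjusted p = 0.203 with an estimated correlation). For the unfolded protein and amino acid stress genes at 4 h, 1 of 15 rose and 7 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.0174, and adjusted p = 0.237 with an estimated correlation). At 1 h 883 genes changed (513 up and 370 down), 214 of them by at least 2-fold. At 2 h 2415 genes changed (1146 up and 1269 down), 434 of them by at least 2-fold, and at 4 h 3937 genes changed (1757 up and 2180 down), 778 of them by at least 2-fold. Without set 1 the counts were 445 at 1 h and 1444 at 2 h.

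LPS and 2MA together raised nearly all measured early response genes at 1 h, and fewer at 2 and 4 h. At 1 h Egr2 rose by 5.40 ± 0.96, Phlda1 by 5.07 ± 0.50, Dusp1 by 4.84 ± 0.40 (adjusted p = 1.33e-17) and Il1b by 3.81 ± 0.44. For the early response transcription factors at 1 h, 19 of 20 rose (19 adjusted over the list alone, camera adjusted p = 2.27e-67). Of the calcium and cAMP responsive genes at 1 h, 13 of 18 rose (16 adjusted over the list alone, camera adjusted p = 1.63e-44). Of the MAPK and G protein feedback genes at 1 h, 9 of 13 rose (10 adjusted over the list alone, camera adjusted p = 2.77e-29). For the NF-kB family and feedback genes at 1 h, 15 of 18 rose (18 adjusted over the list alone, camera adjusted p = 8.18e-50). At 2 h Il1a rose by 4.59 ± 0.14 and Ifnb1 by 4.86 ± 0.40, and at 4 h Cmpk2 by 5.74 ± 0.27 and Il6 by 5.50 ± 0.29. Of the early response transcription factors at 2 h, 15 of 20 rose and 1 fell (15 and 2 adjusted over the list alone, camera adjusted p = 4.41e-12). Among early response transcription factors at 4 h, 9 of 20 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.000307, and adjusted p = 0.124 with an estimated correlation). For the cytokines and chemokines at 2 h, 19 of 26 rose (20 adjusted over the list alone, camera adjusted p = 1.53e-25). For the type I interferon targets at 4 h, 22 of 22 rose (22 adjusted over the list alone, camera adjusted p = 2.37e-35). Of the cell cycle genes at 4 h, 21 of 24 fell (22 adjusted over the list alone, camera adjusted p = 1.13e-12). Of the heat shock genes at 1 h, 1 of 8 rose (2 adjusted over the list alone, camera adjusted p = 0.037, and adjusted p = 0.297 with an estimated correlation). For the cholesterol biosynthesis genes at 1 h, 2 of 8 rose (4 adjusted over the list alone, camera adjusted p = 0.0297, and adjusted p = 0.218 with an estimated correlation). Of the cholesterol biosynthesis genes at 4 h, 1 of 8 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.0102, and adjusted p = 0.124 with an estimated correlation). Sqle, a sterol synthesis enzyme, fell by 1.39 ± 0.15 at 4 h and Lpin1, a phosphatidate phosphatase, fell by 2.29 ± 0.60. At 1 h 632 genes changed (402 up and 230 down), 142 of them by at least 2-fold. At 2 h 2063 genes changed (993 up and 1070 down), 322 of them by at least 2-fold, and at 4 h 3872 genes changed (1730 up and 2142 down), 764 of them by at least 2-fold. Without set 1 the counts were 337 at 1 h and 1299 at 2 h.

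**Figure D3:**
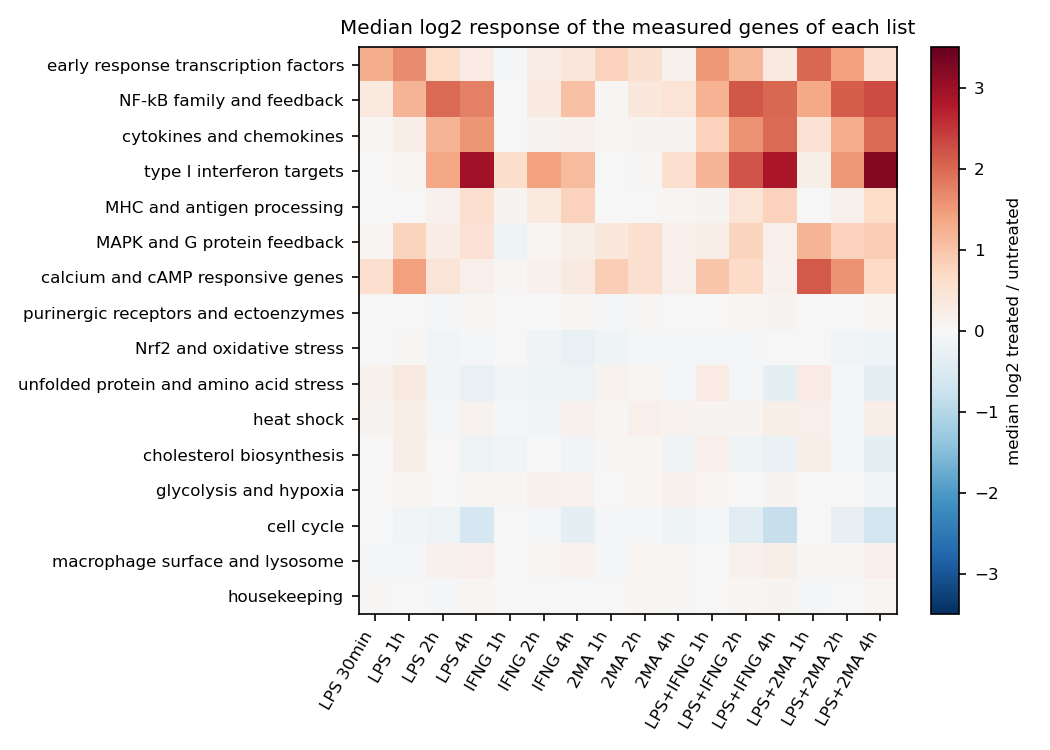
Median log2 response of the measured members of 16 gene lists (y) in the 16 treatment-time groups (x), from blue (below 0) to red (above 0). Among these medians, type I interferon targets had the highest, 3.22 with LPS and 2MA at 4 h, and cell cycle genes the lowest, -0.82 with LPS and IFNG at 4 h.

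The pair was compared with LPS alone to ask what IFNG adds. At 1 h Cxcl9 was higher by 5.14 ± 0.19 (adjusted p = 5.53e-22), Irgm2 by 3.87 ± 0.23, Irf8, a transcription factor of the monocyte lineage, by 3.14 ± 0.21 and Cd274 by 3.16 ± 0.22. At 2 h Iigp1 was higher by 4.51 ± 0.30, F3 by 3.52 ± 0.34, the leukotriene B4 receptor gene Ltb4r1 by 2.73 ± 0.21 and the cAMP-responsive regulator Crem by 2.61 ± 0.20. At 4 h Ly6i was higher by 4.06 ± 0.23, the pro-apoptotic gene Pmaip1 by 2.80 ± 0.25, the Fc receptor Fcgr3 by 2.66 ± 0.21 and the uridine phosphorylase Upp1 by 2.60 ± 0.15. Tlr2, a receptor for bacterial lipoproteins, was lower at 4 h (-1.74 ± 0.21), as were Id3 (-1.62 ± 0.23) and Rgs16 (-1.49 ± 0.37), and Bcl6 was lower at 1 h (-1.19 ± 0.27). Of the type I interferon targets at 1 h, 9 of 22 were higher (13 adjusted over the list alone, camera adjusted p = 7.8e-41). Among type I interferon targets at 4 h, 1 of 22 were lower (1 adjusted over the list alone, camera adjusted p = 0.197). Of the MHC and antigen processing genes at 2 h, 6 of 15 were higher (8 adjusted over the list alone, camera adjusted p = 4.32e-07). For the early response transcription factors at 2 h, 2 of 20 were higher (3 adjusted over the list alone, camera adjusted p = 0.0304, and adjusted p = 0.464 with an estimated correlation, and adjusted p = 0.0689 with the set within time as a block). Among oxidative stress genes at 2 h, 1 of 10 were higher and 1 were lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.0304, and adjusted p = 0.149 with an estimated correlation, and adjusted p = 0.0542 with the set within time as a block). Among cell cycle genes at 2 h, 1 of 24 were lower (3 adjusted over the list alone, camera adjusted p = 0.000277, and adjusted p = 0.0645 with an estimated correlation). Of the purinergic receptors and ectoenzymes at 4 h, 2 of 13 were higher (3 adjusted over the list alone, camera adjusted p = 0.0449, and adjusted p = 0.118 with an estimated correlation, and adjusted p = 0.0927 with the set within time as a block).

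In all, 112 genes were higher with the pair than with LPS and 5 lower at 1 h, 236 and 82 at 2 h, and 302 and 179 at 4 h. With the set within time as a block, the totals were 698 in place of 318 at 2 h and 957 in place of 481 at 4 h. Without set 1 they were 67, 123 and 154 at 1, 2 and 4 h. Without set 2 the total was 199 at 2 h, and without set 3 it was 188 at 2 h and 317 at 4 h.

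Adding 2MA to LPS changed few genes by the test of the difference, which does not pair sets. Acp5, which encodes tartrate-resistant acid phosphatase, an osteoclast marker, was higher at all 3 times, by 1.43 ± 0.17, 1.36 ± 0.17 and 1.51 ± 0.17 (adjusted p = 1.36e-06, 4.82e-06 and 6.97e-07, in 3 of 3 sets). With only the groups of the comparison in the model its adjusted p was 0.0925 at 2 h and 0.0684 at 4 h. At 1 h Il1a was higher by 1.98 ± 0.40, the orphan nuclear receptor Nr4a1 by 1.93 ± 0.38 and the transcription factor Klf4 by 1.18 ± 0.23. At 2 h Egr3 was higher by 1.42 ± 0.30, the cytokine Tslp by 1.06 ± 0.18 and Nfatc1, a calcineurin-activated transcription factor, by 0.85 ± 0.17. At 4 h the cyclin Ccnd2 was higher by 1.79 ± 0.30, Tslp by 1.32 ± 0.18 and the metalloproteinase inhibitor Timp1 by 1.01 ± 0.20, while Fasn, fatty acid synthase, was lower (-0.75 ± 0.17). H2-Q5 was higher at 1 h (0.78 ± 0.10) as the mean of 4 probes, of which 1 gave -0.05. Among calcium and cAMP responsive genes at 1 h, 1 of 18 were higher (10 adjusted over the list alone, camera adjusted p = 2.7e-18). For the calcium and cAMP responsive genes at 2 h, 1 of 18 were higher (5 adjusted over the list alone, camera adjusted p = 1.63e-06). Of the early response transcription factors at 1 h, 2 of 20 were higher (10 adjusted over the list alone, camera adjusted p = 5.59e-21). Among early response transcription factors at 2 h, 1 of 20 were higher (4 adjusted over the list alone, camera adjusted p = 1.26e-07, and adjusted p = 0.0569 with an estimated correlation). Among MAPK and G protein feedback genes at 1 h, 0 of 13 were higher (4 adjusted over the list alone, camera adjusted p = 8.1e-08). Of the cytokines and chemokines at 1 h, 2 of 26 were higher (2 adjusted over the list alone, camera adjusted p = 5.39e-07). Of the NF-kB family and feedback genes at 4 h, 0 of 18 were higher (3 adjusted over the list alone, camera adjusted p = 9.91e-08, and adjusted p = 0.0662 with an estimated correlation). Among cytokines and chemokines at 4 h, 0 of 26 were higher (4 adjusted over the list alone, camera adjusted p = 3.13e-05, and adjusted p = 0.0662 with an estimated correlation).

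In all, 9 genes were higher with LPS and 2MA than with LPS and 0 lower at 1 h, 11 and 0 at 2 h, and 33 and 8 at 4 h by limma. An unadjusted p under 0.05 was found for 251, 556 and 664 genes. With no effect, a share of 0.05 of the 11593 genes would pass, and only the count at 4 h lies above that. The test does not pair sets, which is conservative where sets of the same number move together, as they did here. With arrays scaled to equal spread, 6 were higher and 0 lower at 4 h. Blocking on the set number gave 22, 28 and 80 genes and blocking on the set within time 22, 49 and 201. Without set 1 the counts at the 3 times were 5, 5 and 1, and without set 2 they were 3, 2 and 4. Without set 3 the count was 6 at 2 h and 11 at 4 h.

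Whether the response to LPS and IFNG equalled the sum of the single responses on the log2 scale was tested gene by gene. At 1 h the chemokines Cxcl9 and Ccl12 exceeded the sum by 2.67 ± 0.23 and 2.01 ± 0.28, the kinase Sgk1 by 2.73 ± 0.43 and F3 by 2.22 ± 0.42. At 2 h Nos2, the inducible nitric oxide synthase, exceeded it by 1.35 ± 0.24, and Cxcl9 by 1.43 ± 0.23, a deviation that was -0.14 with arrays scaled to equal spread. Ifit1 and Trim21 deviated downward at 2 h (-1.99 ± 0.29 and -2.15 ± 0.30). For the type I interferon targets at 2 h, 4 of 22 deviated downward (11 adjusted over the list alone, camera adjusted p = 3.38e-26). By 4 h, joint responses smaller than the sum prevailed. Gbp3 deviated by -3.97 ± 0.33 (adjusted p = 2.37e-10), having risen by 4.99 ± 0.53 with LPS, 4.58 ± 0.32 with IFNG and 5.59 ± 0.24 with both. Tgtp1 deviated by -3.82 ± 0.42, Gbp8 by -3.68 ± 0.41 and Igtp by -3.49 ± 0.30. For Gbp3, Tgtp1 and Gbp8 the sum lies above 6.643856, the largest value on any array. A joint response as large as that sum could not be recorded, so part of their shortfall was fixed in advance. Of the type I interferon targets at 4 h, 15 of 22 deviated downward (18 adjusted over the list alone, camera adjusted p = 1.27e-35). Among NF-kB family and feedback genes at 4 h, 6 of 18 deviated downward (12 adjusted over the list alone, camera adjusted p = 8.26e-14). Among MHC and antigen processing genes at 4 h, 5 of 15 deviated downward (9 adjusted over the list alone, camera adjusted p = 1.45e-13). For the cell cycle genes at 4 h, 2 of 24 deviated upward (3 adjusted over the list alone, camera adjusted p = 9.37e-06). Among macrophage surface and lysosome genes at 4 h, 1 of 25 deviated upward and 2 deviated downward (1 and 6 adjusted over the list alone, camera adjusted p = 0.0259, and adjusted p = 0.188 with an estimated correlation, and adjusted p = 0.0548 with the set within time as a block). A few genes exceeded the sum at 4 h, among them Crabp2, a retinoic acid-binding protein, by 2.38 ± 0.41 and Pmaip1 by 1.80 ± 0.31.

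In all, 9 genes deviated from the sum for LPS and IFNG at 1 h (6 larger in size than it and 3 smaller), 43 at 2 h (12 and 31) and 314 at 4 h (37 and 277). By sign, 9 deviated upward and 0 downward at 1 h, 18 and 25 at 2 h, and 98 and 216 at 4 h by limma. At 1 h 192 had an unadjusted p under 0.05, below the share of 0.05 of the 11593 genes that would pass with no effect. With arrays scaled to equal spread these splits were 5 and 1, 6 and 50, and 39 and 160. That scaling gives each array its own factor. At 2 h LPS and IFNG arrays had SDs of 0.60 to 0.69, those of LPS 0.46 to 0.59 and those of IFNG 0.35 to 0.51. The scaling can thus shrink joint responses against single ones, so these splits do not show whether the deviations hold. Blocking on the set number gave 14 genes at 1 h and 476 at 4 h, and blocking on the set within time 24 and 641. Without set 1 the counts at 1, 2 and 4 h were 3, 7 and 117, and without set 2 they were 3, 12 and 138.

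**Figure D4:**
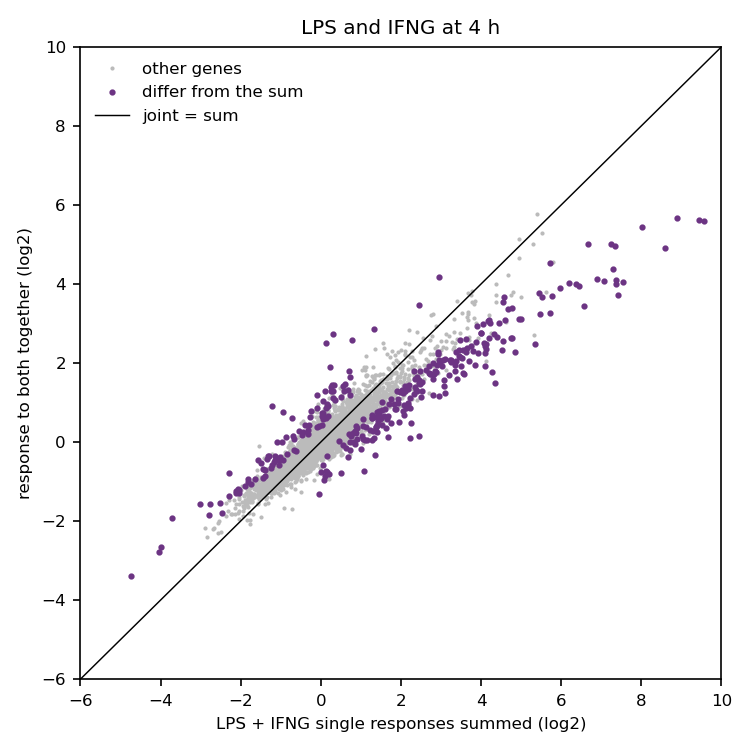
Response to LPS and IFNG together at 4 h (y, log2) against the sum of the single responses (x, log2), 1 point per gene, means over sets; the line marks equality. Purple points are the 314 genes that differ from the sum, of which 277 were smaller in size than it. No array value exceeded 6.643856, so a larger sum could not be matched.

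For LPS and 2MA few genes left the sum. Acp5 exceeded it at 1, 2 and 4 h by 1.29 ± 0.20, 1.06 ± 0.20 and 1.18 ± 0.20 (adjusted p = 0.00257, 0.0486 and 0.00299), while its responses to 2MA alone were 0.14 ± 0.056, 0.30 ± 0.20 and 0.33 ± 0.24 and did not pass the test. With arrays scaled to equal spread the deviation of Acp5 passed at 1 h but not at 2 h (adjusted p = 0.475) or 4 h (adjusted p = 0.514), and it passed at no time without set 1 or without set 2. The scaling changes joint and single responses by different factors, so it does not decide whether the deviation holds. Tslp exceeded the sum at 4 h by 1.28 ± 0.22. Ccl7 deviated downward at 2 h (-1.77 ± 0.27), though 1 of its 3 probes gave 0.08, and Odc1 (-1.30 ± 0.25) and Samsn1 (-1.06 ± 0.18) did so at 4 h. For the early response transcription factors at 1 h, 0 of 20 deviated downward (6 adjusted over the list alone, camera adjusted p = 0.000222, and adjusted p = 0.339 with an estimated correlation). For the NF-kB family and feedback genes at 2 h, 0 of 18 deviated downward (0 adjusted over the list alone, camera adjusted p = 1.32e-05, and adjusted p = 0.345 with an estimated correlation). Among type I interferon targets at 4 h, 0 of 22 deviated downward (0 adjusted over the list alone, camera adjusted p = 6.49e-06, and adjusted p = 0.277 with an estimated correlation). In all, 2 genes deviated at 1 h, 2 at 2 h and 7 at 4 h, and 2, 1 and 2 of them were larger in size than the sum. At 2 h 1 deviated upward and 1 downward, and 2 and 1 with centred arrays. Blocking on the set number gave 4 genes at 2 h and 14 at 4 h, and on the set within time 13 and 34. Without set 1 the count was 0 at each time, and without set 2 it was 0, 1 and 1. Without set 3 it was 6 at 1 h and 5 at 2 h. With all sets, 292, 318 and 422 genes had an unadjusted p under 0.05 by limma. Each count lies below the share of 0.05 of the 11593 genes that would pass with no effect.

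LPS and IFNG shared more genes at 4 h than at 1 h. At 4 h they shared 503 risen genes, where independent lists would share 92.9, and 543 fallen genes against 110, while 66 went in opposite directions. At 1 h they shared 23 risen genes against 3.63. LPS and 2MA shared 55 risen genes at 1 h against 2.88, 85 at 2 h against 9.33 and 122 at 4 h against 21. Without set 1 only 20, 12 and 13 genes changed with 2MA at these times, and the overlaps could not exceed those counts. To mimic no effect, deviations from the group means had their signs turned at random, alike for all groups of a set and time. Over 10 draws the mean overlap was 4.8 genes at 4 h for LPS and IFNG and 11.3 at 2 h for LPS and 2MA. The highest draws were 39 and 78 (and 43 at 4 h for LPS and 2MA). With 3 sets few sign patterns exist, and all signs alike give means of 0 and no overlap, so the mean overlaps run low. These draws count risen and fallen genes, and LPS and 2MA at 2 h shared 27 fallen genes beside the 85 risen ones, not far above the highest draw. Across genes, the responses to LPS and IFNG correlated at 0.195, 0.329 and 0.656 at 1, 2 and 4 h, and those to LPS and 2MA at 0.448, 0.488 and 0.501. With no effect, simulated correlations were 0.426, 0.248 and 0.409 for the first pair and 0.297, 0.264 and 0.329 for the second. The covariances were 0.00924, 0.0305 and 0.115 for LPS and IFNG and 0.0246, 0.0309 and 0.045 for LPS and 2MA, against simulated values of 0.00435, 0.00392 and 0.00716 and 0.00382, 0.00567 and 0.00631. Over pairs of different sets, which leave out spread shared within a set, they were 0.004, 0.0257 and 0.106 and 0.0198, 0.0238 and 0.0369.

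The purinergic, glycolysis, heat shock and housekeeping lists gave few calls against untreated cells. Among purinergic receptors and ectoenzymes with LPS and IFNG at 4 h, 5 of 13 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.00891). There P2ry6 rose by 1.03 ± 0.54 and P2rx7 fell by 0.27 ± 0.12. Of the glycolysis and hypoxia genes with 2MA at 4 h, 0 of 11 rose (0 adjusted over the list alone, camera adjusted p = 0.00109, and adjusted p = 0.0699 with an estimated correlation). Of the housekeeping genes with LPS at 4 h, 1 of 9 rose (1 adjusted over the list alone, camera adjusted p = 0.618). Among heat shock genes with LPS at 4 h, 2 of 8 rose (2 adjusted over the list alone, camera adjusted p = 0.425). The inducible chaperone Hspa1a was at 1.40 ± 0.93. Of the macrophage markers, 5 of 7 were measured, and after LPS at 4 h Adgre1 (0.94 ± 0.25), Spi1 (0.66 ± 0.35) and Cd68 (0.24 ± 0.14) rose and Csf1r fell (-0.94 ± 0.23). None of the 4 measured B cell markers or 5 fibroblast markers passed the test in any group by limma. The T cell marker Cd4 rose with LPS at 1 h (0.37 ± 0.066) and 4 h (0.21 ± 0.17) and at 1 h with LPS and IFNG (0.49 ± 0.085) and with LPS and 2MA (0.37 ± 0.092), and Cd3e rose with LPS and IFNG at 2 h (0.40 ± 0.13). The epithelial marker Krt19 rose at 4 h with IFNG (0.33 ± 0.32) and with LPS and 2MA (0.30 ± 0.20). The dendritic cell marker Zbtb46 rose at 2 h with LPS (0.29 ± 0.16) and with LPS and 2MA (0.53 ± 0.32). Acp5, on the osteoclast list, rose with LPS and 2MA by 1.70 ± 0.37, 1.95 ± 0.25 and 2.42 ± 0.37 at 1, 2 and 4 h, while the median of the 3 measured osteoclast markers was 0.01, 0.06 and 0.11.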

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

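All tests of explanations in this part were chosen after the results they explain were seen (those of compression, traces of LPS and dim spots were replaced after a first version was seen), while the splits of the samples were planned. Deviations from the sum of 2 responses stand out as differences between groups by a test of the difference: 9, 43 and 314 genes for LPS and IFNG at 1, 2 and 4 h, and 2, 2 and 7 genes for LPS and 2MA. The response to LPS differed over its 4 times in 1941 genes. Among probes left out of the tests for missing sets, 71 had all 6 arrays of some group on 1 side of 0 with a mean of at least 1, and they carry 58 named genes, 26 of which were tested by another probe. No array stood apart in 32 checks of groups of arrays.

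The joint response to LPS and IFNG at 4 h fell short of the sum in 256 genes that both ligands moved the same way, 200 up and 56 down. The median size was 2.39 for the sum and 1.33 for the joint response. Compression of large ratios on the array keeps the larger ratio at least as large. It is argued against where the joint response was smaller than that to LPS by the test, in 50 genes. In 64 of the other 206 genes the summed size was under 2, while 195 genes on the array had a joint response of at least 2. That count argues against a limit common to all probes, but leaves compression of single probes among the 64 open. In the remaining 142 genes compression and a limit of the cells cannot be told apart, since 0 of them reached the summed size in another group. A sum above 6.643856, the largest value on any array, could not be reached in any group, so there part of the shortfall was fixed in advance. A handling effect shared by all treated dishes, as the whole cause, is argued against by a median 2MA response of 0.211 of the median shortfall (quartiles over genes 0.069 and 0.378). The 2MA sets at 4 h correlated at only 0.0942, 0.336 and -0.03 across genes, so a smaller shared effect stays open. Untreated RNA shared between treatments, if it was, would also enter this shortfall and was not tested apart. Traces of LPS in the IFNG as the whole cause would need IFNG to act like LPS. At 4 h the ratio of the IFNG to the LPS response in the 256 genes had a median of 0.643 (quartiles 0.387 and 0.902). In the 84 genes risen at 30 min of LPS it was 0.0229 at 1 h (quartiles -0.107 and 0.226), where 10 of them rose and 4 fell with IFNG. These ratios differ in time and genes, so they argue only against traces that act by 1 h. With IFNG at 4 h Csf3, Ccl4 and Il1b were at 0.03, 0.03 and 0.19, against 4.18, 3.84 and 4.75 with LPS. Other LPS genes did rise with IFNG at 4 h. Single sets of Tnf were at 1.14 to 1.90, against 2.74 to 3.835 with LPS. Those of Egr1 were at 1.84 to 3.74, against 1.91 to 3.09 with LPS. Smaller or later-acting traces stay open, and the median IFNG response of the 84 genes at 4 h was 0.396. A limit on transcription that either ligand alone reaches stays an untested hypothesis, and in 164 genes the joint response was below the larger single response.

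In all, 15 probes were at exactly 0 on at least 5 of 6 LPS arrays at 4 h and on at most 1 of 6 2MA arrays at 1 h, against 2 probes with the converse pattern. Among the 15 was 1 probe each of Acod1, Ccl4, Cxcl10, Cxcl2, Ifit2 and Rsad2. A missing response to LPS is argued against by other probes of 2 of these genes, with a median size of 4.56 at 4 h. Saturated bright spots left out before the values were made may account for them, but the values are ratios and give no brightness. A test asked only whether these probes rose with LPS. Of 12 probes with at least 4 arrays at some LPS time, 10 were above 1 at the latest such time, a share of 0.833. Induced genes would give that share whether their spots were bright or not, so saturation stays open. A first version of that test, at LPS 1 h, found 7 of 13 above 1 and was replaced after it was seen. In the later version Sqstm1 was at 0.39 and an unnamed probe at 0.92, while Ebp, Junb and another unnamed probe had too few arrays. These probes of Ccl4 and Cxcl2 were at 0 on 6 of 6 LPS arrays at 4 h, but on only 1 and 2 of 6 with LPS and IFNG, which was not explained. The Cxcl2 mean of -1.27 at LPS 4 h thus came from its other probe. Dim spots are argued against for Ccl4 and Ifit2, whose other probes rose by 3.84 or more at LPS 4 h (lowest single set 3.69). For the other 13 probes dim spots stay open: their share of zeros on the 2MA arrays at 2 h was 0.231 (0.154 to 0.308 per array, all in 4 probes), and the choice of probes by their 2MA arrays at 1 h favours a low share. No biological explanation was tested.

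The pair of Ifit3 probes differed in time course. The tested probe was at 3.03 at LPS 30 min and the other at -0.04 (3 sets each), when no other measured type I interferon target passed the test. The early-rising probe may read another transcript: over the groups it correlated at 0.49 with the mean of 21 other type I interferon targets and at 0.93 with Tnf, against 0.954 for the other probe over 14 groups. No biological explanation was tested.

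Other splits of the same sets, made by turning the sign of sets or exchanging sets between groups, were counted beside each result, and the real split alone gave a result as large in each case (1 split). For responses to a treatment there are 4 splits, too few for a share under 0.05; the real count and the highest other were 121 against 2 for LPS at 30 min, 650 against 2 for LPS at 1 h, 1857 against 48 for LPS at 2 h, 3315 against 12 for LPS at 4 h, 131 against 1 for IFNG at 1 h, 398 against 2 for IFNG at 2 h, 1426 against 6 for IFNG at 4 h, 163 against 5 for 2MA at 1 h, 154 against 0 for 2MA at 2 h, 232 against 1 for 2MA at 4 h, 883 against 19 for LPS with IFNG at 1 h, 2415 against 3 for LPS with IFNG at 2 h, 3937 against 17 for LPS with IFNG at 4 h, 632 against 3 for LPS with 2MA at 1 h, 2063 against 4 for LPS with 2MA at 2 h and 3872 against 25 for LPS with 2MA at 4 h. For differences from LPS there are 10 splits, again too few, with 117 against 1 for LPS with IFNG against LPS at 1 h, 318 against 10 for LPS with IFNG against LPS at 2 h, 481 against 29 for LPS with IFNG against LPS at 4 h, 9 against 0 for LPS with 2MA against LPS at 1 h, 11 against 5 for LPS with 2MA against LPS at 2 h and 41 against 15 for LPS with 2MA against LPS at 4 h. Sets of the same number are paired in these comparisons, and the 3 other splits that part all 3 pairs, as the real one does, gave 0 genes by limma in each; the highest others above 0 came from the 6 splits that part 1 pair. For deviations from the sum, 4 splits are too few, with 9 against 1 for the sum of LPS and IFNG at 1 h, 43 against 0 for the sum of LPS and IFNG at 2 h, 314 against 0 for the sum of LPS and IFNG at 4 h, 2 against 0 for the sum of LPS and 2MA at 1 h, 2 against 0 for the sum of LPS and 2MA at 2 h and 7 against 0 for the sum of LPS and 2MA at 4 h. For the LPS times, 1 of 100 splits, the real one, gave as many as 1941 genes, and the highest other gave 1637. That share is under 0.05. Only the LPS sets were reordered, while the test takes its spread from all 16 groups. Genes that change with time can therefore pass in a random order too. The 1637 is thus not a count expected with no effect, and no conclusion about the 1941 genes is drawn from it.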

How the results depend on the processing

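Keeping zeros as 0 was chosen only after the data were seen; the other alternatives were planned. Of 1902 pairs of a named gene and a comparison (323 genes), 1895 kept direction and call with centred arrays (7 lost the call), 1880 with all 96 arrays and a dye term (22 lost), 1837 with zeros kept as 0 (65 lost) and 1647 with arrays scaled to equal spread (254 lost, 1 turned). With only the groups of a comparison in the model 1562 kept the call and 236 lost it. Without set 1, 2 or 3, 1416, 1574 and 1694 kept it and 486, 328 and 208 lost it. With each probe alone 1058 kept it, 164 lost it and 19 turned, and with probes that had a value on all arrays 1527 kept it, 28 lost it and 4 turned. Both replicate block settings kept all 265 pairs they apply to. Of 208 calls over the 17 lists, 88 were lost with an estimated correlation, 47 with fry, 2 with centred arrays and 5 with the set within time as a replicate block.

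Counts that moved by more than 1.5 times follow, and the cause was not tested unless stated. Scaling to equal spread gave 188 for LPS at 30 min, 213 for IFNG at 1 h, 172 and 184 for LPS with IFNG against LPS at 2 and 4 h, 4 and 6 for LPS with 2MA against LPS at 2 and 4 h, 199 for the sum of LPS and IFNG at 4 h and 1 and 0 for the sum of LPS and 2MA at 1 and 2 h. That scaling multiplies each array by its own factor, so it changes the size of responses relative to each other. All 96 arrays with a dye term gave 488, 285 and 475 for 2MA at 1, 2 and 4 h, 478 for LPS with IFNG against LPS at 2 h, 35, 50 and 115 for LPS with 2MA against LPS at 1, 2 and 4 h, 23, 91 and 485 for the sum of LPS and IFNG at 1, 2 and 4 h and 14, 21 and 42 for the sum of LPS and 2MA at 1, 2 and 4 h. Each probe alone, which counts probes, gave 16 and 7 for LPS with 2MA against LPS at 1 and 2 h, 14 for the sum of LPS and IFNG at 1 h and 4 and 13 for the sum of LPS and 2MA at 2 and 4 h. Probes with a value on all arrays, fewer of which were tested, gave 1 for the sum of LPS and 2MA at 1 h. A robust prior gave 1 for the sum of LPS and 2MA at 2 h. The comparison's own groups alone, with fewer sets in the model, gave 1030 for LPS at 2 h, 14 and 36 for 2MA at 2 and 4 h, 1194 for LPS with IFNG at 2 h, 948 for LPS with 2MA at 2 h, 99 and 164 for LPS with IFNG against LPS at 2 and 4 h and 2 and 3 for LPS with 2MA against LPS at 2 and 4 h. Zeros kept as 0 gave 4 and 13 for the sum of LPS and 2MA at 2 and 4 h.

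With sets paired by a replicate block of set number, the counts were 22, 28 and 80 for LPS with 2MA against LPS at 1, 2 and 4 h, 14, 67 and 476 for the sum of LPS and IFNG at 1, 2 and 4 h and 4, 4 and 14 for the sum of LPS and 2MA at 1, 2 and 4 h. With the replicate block of set within time they were 698 and 957 for LPS with IFNG against LPS at 2 and 4 h, 22, 49 and 201 for LPS with 2MA against LPS at 1, 2 and 4 h, 24, 120 and 641 for the sum of LPS and IFNG at 1, 2 and 4 h and 13, 13 and 34 for the sum of LPS and 2MA at 1, 2 and 4 h.

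Leaving out each set in turn gave these ranges of counts, lowest to highest. Against untreated cells they were 76 to 86 for LPS at 30 min, 273 to 528 for LPS at 1 h, 999 to 1656 for LPS at 2 h, 2136 to 2977 for LPS at 4 h, 80 to 128 for IFNG at 1 h, 220 to 313 for IFNG at 2 h, 826 to 1376 for IFNG at 4 h, 20 to 351 for 2MA at 1 h, 12 to 213 for 2MA at 2 h, 13 to 194 for 2MA at 4 h, 445 to 795 for LPS with IFNG at 1 h, 1444 to 2610 for LPS with IFNG at 2 h, 2744 to 3875 for LPS with IFNG at 4 h, 337 to 532 for LPS with 2MA at 1 h, 1299 to 1716 for LPS with 2MA at 2 h and 2770 to 3523 for LPS with 2MA at 4 h. For differences from LPS they were 67 to 104 for LPS with IFNG against LPS at 1 h, 123 to 199 for LPS with IFNG against LPS at 2 h, 154 to 329 for LPS with IFNG against LPS at 4 h, 3 to 11 for LPS with 2MA against LPS at 1 h, 2 to 6 for LPS with 2MA against LPS at 2 h and 1 to 11 for LPS with 2MA against LPS at 4 h. For deviations from the sum they were 3 to 9 for the sum of LPS and IFNG at 1 h, 7 to 58 for the sum of LPS and IFNG at 2 h, 117 to 269 for the sum of LPS and IFNG at 4 h, 0 to 6 for the sum of LPS and 2MA at 1 h, 0 to 5 for the sum of LPS and 2MA at 2 h and 0 to 10 for the sum of LPS and 2MA at 4 h. For the LPS times the range was 789 to 1547.

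The deviation of Cxcl9 from the sum of LPS and IFNG at 2 h turned to -0.14 with arrays scaled to equal spread, which can shrink joint responses against single ones. Among all 1914 genes with several probes, some had probes called in opposite directions and were averaged all the same. At 4 h these were 14 genes with LPS, 18 with LPS and IFNG and 19 with LPS and 2MA. Among the named genes, 1 probe of each of 7 genes turned with each probe alone. The probe of Ccl22 gave -0.15 for LPS at 1 h and -0.11 for LPS at 2 h. For Lif it gave -0.13 for LPS at 1 h, -0.00968 for LPS with IFNG at 1 h, -0.0871 for LPS with 2MA at 1 h and -0.0305 for LPS with 2MA at 4 h. The probe of Tlr4 gave 0.0246 for LPS at 1 h, 0.0401 for LPS with IFNG at 1 h and 0.0564 for LPS with IFNG at 2 h. For Ccl7 it gave -0.0517 for 2MA at 1 h, -0.19 for 2MA at 2 h, -0.00315 for LPS with 2MA against LPS at 1 h and 0.0762 for the sum of LPS and 2MA at 2 h. The probe of Adora3 gave 0.066 for LPS with 2MA at 2 h and -0.12 for LPS with IFNG against LPS at 4 h. For Ywhaz it gave -0.0446 for LPS with 2MA at 4 h and -0.0455 for the sum of LPS and IFNG at 4 h. The probe of H2-Q5 gave -0.0486 for LPS with 2MA against LPS at 1 h and -0.26 for the sum of LPS and 2MA at 1 h. With probes that had a value on all arrays, that probe is the only one left for Lif, and the values were -0.13 for LPS at 1 h, -0.00968 for LPS with IFNG at 1 h, -0.0871 for LPS with 2MA at 1 h and -0.0305 for LPS with 2MA at 4 h. The cause was not tested, and the design does not tell a probe that reads another transcript from a weak probe. Probes without a value on some arrays limit which genes could be tested, and signal over background is not given in the sources used here.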

Other observations

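The values of left-out probes below were looked up after the results were seen, and none of these probes was tested; each is a mean over 6 arrays, all above 0. Acod1, which makes the antimicrobial metabolite itaconate, was at 3.73 with LPS at 1 h, 4.90 with IFNG at 4 h and 2.61 with 2MA at 2 h. The chemokine Ccl5 was at 3.79 with LPS at 4 h and 3.77 with LPS and IFNG, while another probe of it that was tested gave 0.65 and 0.44. A probe of Cxcl11, a chemokine induced by interferons, was at 4.06 with IFNG at 2 h and 4.59 with LPS at 4 h. The chemokine Ccl2 was at 2.21 with 2MA at 4 h and 2.24 with IFNG at 4 h. Hcar2, a receptor for nicotinic acid, was at 3.29 with LPS and IFNG at 2 h (tested probe 2.99), and Fabp4, a fatty acid-binding protein, at 2.01 with LPS at 4 h (tested probe 0.65).

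In the 2MA groups at 2 and 4 h, responses of set 2 correlated less with those of the other sets. Responses of set 2 correlated across genes at 0.417, 0.0713 and 0.0942 with set 1 and at 0.124, -0.33 and -0.03 with set 3 at 1, 2 and 4 h, while sets 1 and 3 correlated at 0.485, 0.552 and 0.336. Before turning, the dye-swapped arrays of set 2 correlated at 0.239, 0.236 and 0.396 and those of set 3 at 0.00308, 0.183 and -0.248, so that at 1 and 2 h both sets lay above 0.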
